A study of Arabidopsis thaliana with 8 samples.

How the data were processed

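Transcript levels were measured on 8 Agilent 2-colour arrays of Arabidopsis thaliana. Each array carried labelled RNA of Alc::LHY plants, which hold an ethanol-inducible copy of LHY, beside RNA of wild-type plants. The labels give 4 times after ethanol with 2 replicate arrays each, called S and I. The last time was 9 h in replicate S and 8 h in replicate I, and the pair was treated as a single 8-9 h group. Alc::LHY RNA was labelled with Cy5 in replicate S and with Cy3 in replicate I. The 4 arrays of a replicate lay on a single slide, so dye, replicate and slide are the same split and cannot be told apart. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

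Per the file headers, the deposited scanner files were written by Feature Extraction 10.7.3.1 with protocol GE2_105_Dec08. The submitters' processing notes name the same software and version. The deposited median signal and median background of each spot are intensity values on a linear scale in arbitrary units, 1 value per dye. The deposited log ratio of the scanner files is log10 of Cy5 over Cy3 after the scanner software's own background and dye correction. The authors' series matrix holds the same log10 ratios turned so that Alc::LHY is the numerator. Each of its columns correlated with the turned scanner ratio at 0.999999 or higher, and the values differed by at most 0.00425. Scale and direction of the matrix are thereby known, and no further centring was found. The column medians were 0 on all 8 arrays. The log ratio was exactly 0 for 23.1% to 28.9% of the spots of an array. The plan named mean spot signals, but the files hold no such column, so median spot signals took their place. The scanner file of replicate S at 0 h holds rounded values, and the largest difference from the matrix was on that array.

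Each array held 45220 features, of which 1417 were controls. The background was corrected with the normexp method (offset 50) on all spots. Control spots then had weight 0 in a within-array loess normalization and were left out, as were 161 spots with an outlier flag over the 8 arrays. After plain subtraction of the background and before loess, the median log2 ratio of an array lay between -1.67 and 1.12 in the Alc::LHY over wild type direction. No spot was saturated (0 spots). The median Cy3 signal of an array was 54 to 73 units and the median Cy5 signal 121 to 146 units. Between 50.8% and 58.9% of the spots were well above background in Cy3, and 57.6% to 63.3% in Cy5. The number of arrays limits the precision of all values. Ratios of the spike-in controls rose with their known ratios with slopes of 0.839 to 0.975 on the log scale.

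Spots of a probe were averaged, which left 43603 probes. A probe was kept when it was well above background in either channel on at least 2 of the 8 arrays, which 28465 probes were. It also needed a value on at least 6 arrays. A gene with several probes was represented by the probe with the highest mean intensity. Of 5402 genes with several probes, 0 had probes with opposite ratios beyond 1 log2 unit at 4 h. Other probes of some named genes gave ratios nearer 0, such as -0.75 for EXPA8, -0.34 for LHCB2.2, -0.44 for LHB1B1 and -0.23 for PIF1 at 4 h and -0.97 for CYP79F1 and -0.40 for GSTF12 at 8-9 h. The tests covered 21471 genes or unnamed transcripts, 18497 of them with a locus. Accessions of the probe annotation were named through the TAIR10.1 gene table, in which 26259 of 27803 accessions were found. The files' own annotation refers to an older build, so no coordinates are given. Probe sequences were not analysed here, so signal shared between near-identical gene copies (LHCB and RBCS genes, KIN1 and COR6.6) cannot be separated.

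Ratios were turned to Alc::LHY over wild type and fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, data.table in version 1.17.8). The model had a coefficient for each of the 4 times and a dye term, and left 3 residual degrees of freedom. The moderated test added 3.59 prior degrees of freedom. Differences between times were contrasts of the same fit. A gene was called when its Benjamini-Hochberg adjusted p within the comparison was under 0.05. Errors given with ± are standard errors of the fit, each time resting on n = 2 arrays. Changes over time within a line came from a separate-channel fit of 16 channels after Aquantile normalization between arrays. It had 8 line-and-time groups, a dye term and a replicate term, 6 residual degrees of freedom, an intraspot correlation of 0.333 and 21412 genes. Where a gene was well above background on no array of 1 of the groups compared, only a bound is given as "at least N-fold". It sets the bright group's mean against the higher of the dim signal and the lowest signal well above background. Such bounds come from normalized channel levels and remain open to dye bias.

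Before the data were examined, 15 gene lists with 226 loci were fixed, of which 201 were measured. They cover evening and daytime clock genes, morning MYB-like and LNK clock genes, clock outputs and flowering time, cold response, abscisic acid (ABA) synthesis and breakdown, ABA signalling, ABA and drought response, low oxygen and ethanol metabolism, photosynthesis, PIF, shade and auxin growth genes, the phenylpropanoid and flavonoid pathway, starch metabolism, heat shock, defence with jasmonate and wounding, and root markers. Each list was tested against all other genes with camera in limma at a preset correlation between genes of 0.01, adjusted over the 15 lists. The set tests of the genotype comparisons leave out genes without a value on every array, so they cover 20 of 21 photosynthesis genes and 13 of 14 evening and daytime clock genes. The test was repeated with the correlation estimated from the residuals. The named genes follow a rule fixed at the same point. For each time the rule takes LHY, all measured members of both clock lists, and the 8 largest called ratios each way with the same sign on both arrays. It adds the 4 members with the smallest p of every other list that passes its test and up to 2 called members of the remaining lists. For changes over time it takes the 5 largest each way, LHY and the clock lists. Genes named outside the rule are said to be chosen after their values were seen.

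The fit was tested on simulated data. With 200 of 21412 genes changed in a simulated 2 h comparison, 66% were recovered at 1 log2 unit with 5 false calls, and 92.5% at 2 log2 units with 11 false calls. In a simulated wild-type change to 4 h over 4000 genes, 82% of 200 changed genes were recovered at 1 log2 unit with 7 false calls, and 95.5% at 2 log2 units with 14 false calls. In limma's camera test a simulated list of 20 genes shifted by 0.5 log2 units passed, and 1 of 50 unshifted lists had an unadjusted value under 0.05. The simulated genes were drawn independently, so this does not test the preset correlation on lists whose genes move together. In the genotype comparisons the estimated correlation of the real lists ran from -0.016 for ABA signalling to 0.83 for heat shock.

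The alternatives were the fit without the dye term, no background subtraction, the scanner software's log ratio, the authors' matrix, median centring in place of loess, Aquantile after loess, no filter and a strict filter on dim probes (20934 probes well above background in both channels on all arrays), the mean of a gene's probes, an intensity trend in the prior, array weights, each array left out in turn, and the 8 h and the 9 h array as separate times. The wild-type fit was repeated without the replicate term and with quantile normalization of all channels. Groups of 2 arrays allow no test for single outlying arrays and no count of other splits of the samples.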

Results

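Arrays with 2 dyes were used to follow gene expression after the induction of LHY, a MYB-like transcription factor of the morning loop of the plant circadian clock that represses evening genes. Seedlings were grown on agar for 2 weeks under a 12 h photoperiod and moved to continuous light. Ethanol was given 17 h later, as 5 ml to the roots and on filter paper of 3 cm2. In Alc::LHY plants, ethanol switches on an additional copy of LHY. Wild-type plants shared their Col-0 background, and the labels give a single treatment for both dyes of an array. Samples were taken at 0, 2, 4 and 8 or 9 h after ethanol, with 2 arrays per time, and each array compared both lines directly. No line held the ethanol switch without the additional copy of LHY. Differences after ethanol therefore cannot be assigned to LHY apart from the switch with ethanol or other differences between the lines. All ratios are log2 of Alc::LHY over wild type. The standard deviation of the ratios over probes was 0.21 to 0.32 on the arrays at 0 h and 0.51 to 0.67 on those after ethanol. The ratios of the 2 replicates correlated across genes at 0.65 at 2 h, 0.81 at 4 h and 0.87 at 8-9 h. At 0 h they correlated at -0.39 and, before turning the swapped dye, at 0.39. Genes are not independent replicates in these correlations.

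LHY (AT1G01060) was measured by 1 probe, which was dim. It stood 0.57 ± 0.13 above wild type at 2 h (adjusted p = 0.0301). On single arrays the value was 0.97 in replicate S and 0.17 in replicate I. Since the probe was not well above background in wild type at 2 h, the difference is a bound of at least 1.49-fold. The ratio of LHY was 0.38 at 4 h (adjusted p = 0.0534) and 0.24 at 8-9 h (adjusted p = 0.181). At 0 h the probe was not well above background in either dye on either array, so its ratio of 0.02 compares background with background. The position of the probe within the transcript is not given in the sources used here, so whether it reads the induced copy fully is not known. The call at 2 h was lost without the dye term (0.57, adjusted p = 0.113) and with median centring in place of loess (0.67, adjusted p = 0.243). It was also lost without the replicate S array at 2 h (0.30, adjusted p = 0.424), without the replicate I array at 2 h (0.84, adjusted p = 0.0583) and without either array at 8-9 h (0.57, adjusted p = 0.0502). The scanner software's ratio and the authors' matrix put LHY higher, at 2.51 at 2 h (adjusted p = 0.00169 and 0.00168), 1.18 at 4 h (adjusted p = 0.00617) and 0.58 at 8-9 h (adjusted p = 0.0331). At 4 h LHY also passed without background subtraction (0.50, adjusted p = 0.013), with an intensity trend (0.38, adjusted p = 0.0473) and without either array at 2 h (0.38, adjusted p = 0.0363).

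The transcript with the largest ratio at 2, 4 and 8-9 h was TA44692_3702, an assembled sequence with no gene name in the files. It stood 6.33 ± 0.72 above wild type at 2 h, 9.17 ± 0.72 at 4 h and 8.03 ± 0.72 at 8-9 h (adjusted p = 0.00328, 0.000469 and 0.00066). At 0 h its ratio was 0.24 in replicate S and 2.60 in replicate I.

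Before induction the comparison asks whether the lines differed at the start. AT3G21310 was 4.31-fold higher in Alc::LHY at 0 h (2.11 ± 0.11, adjusted p = 0.0102). AT3G28899 was lower by at least 10.4-fold (adjusted p = 0.0153), and it was not well above background in Alc::LHY. AT3G25150 was lower as well (-1.93 ± 0.13, adjusted p = 0.0153). These 3 of 21471 genes passed the threshold in limma, and 501 genes had an unadjusted p under 0.05. None of the clock genes passed. No member of the ABA and drought response list passed either, yet its 11 members together stood slightly higher (median 0.27, adjusted p = 0.0387, and adjusted p = 0.822 with an estimated correlation). The 21 light-harvesting and Rubisco small subunit genes behaved alike (median 0.18, adjusted p = 0.013, and adjusted p = 0.822 with an estimated correlation). With median centring the count at 0 h was 0 in limma, with 86 genes at an unadjusted p under 0.05. It was 20 with the scanner software's ratio (18 higher and 2 lower), 11 without background subtraction (9 and 2), 4 without the dye term (3 and 1), and 0 or 1 without any single array at 0, 2 or 4 h.

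At 2 h after ethanol, the highest ratios of single genes lay further from 0 than the lowest. SBTI1.1, a subtilisin-like protease, stood 43.9-fold higher in Alc::LHY (5.46 ± 0.15, adjusted p = 3.87e-05). EXL4, a member of the EXORDIUM-like family, was 26.3-fold higher (4.72 ± 0.23), and AT3G63360 was at least 22.5-fold higher. AT1G20030 (4.18 ± 0.12), AT4G29640 (4.84 ± 0.24), AT5G62730 (4.72 ± 0.25) and DGR1 (4.05 ± 0.56) completed the named genes with the highest ratios after TA44692_3702. AT3G28899 had the lowest (-2.18 ± 0.22), but it had been lower by at least 10.4-fold before ethanol. Next came AT3G62550 (-2.05 ± 0.42), the BTB and TAZ domain gene BT1 (-2.0 ± 0.25), AT1G60590 (-1.95 ± 0.13), AT1G23205 (-1.90 ± 0.15), the transcription factor gene MYB47 (-1.87 ± 0.20) and AT1G52000 (-1.85 ± 0.18). A transcript without a gene name, known only by an accession, lay between AT1G23205 and MYB47 (-1.896 ± 0.15).

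Among the 14 evening and daytime clock genes, 2 were lower in Alc::LHY at 2 h, while 14.2% of all genes tested were called. CHE, which encodes a TCP factor that binds the CCA1 promoter, was lower (-0.98 ± 0.17, adjusted p = 0.0118), and so was LUX, a component of the evening complex (-0.93 ± 0.22, adjusted p = 0.0392). PRR5, a pseudo-response regulator, had a ratio of -0.80 (adjusted p = 0.059), TOC1 of -0.68 (adjusted p = 0.0664) and BOA of 0.84 (adjusted p = 0.0511). When adjusted over the list alone, 1 evening and daytime gene was higher and 4 were lower. None of the 13 morning MYB-like and LNK genes passed, by either adjustment, and their median was -0.09. Among them RVE2 had a mean log2 level of 9.69 in Alc::LHY and 10.99 in wild type. The 23 ABA signalling genes stood lower together (median -0.34, adjusted p = 0.0164), a call lost with an estimated correlation (adjusted p = 0.549 with an estimated correlation). Of these 23, 5 were lower and 1 was higher (8 and 1 adjusted over the list alone). The receptor genes PYL4 (-0.93 ± 0.16) and PYL6 (-0.68 ± 0.14) and the kinase gene SNRK2.3 (-0.63 ± 0.12) were lower, and HAI2, which encodes a protein phosphatase of the pathway, was higher (1.5 ± 0.28).

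Single members of other lists differed between the lines at 2 h without their list passing. NCED4, a carotenoid cleavage gene, was lower (-1.53 ± 0.12). Of the 16 clock outputs 3 were lower, among them COL1 (-1.27 ± 0.14) and BBX25 (-0.98 ± 0.14), and 1 was higher. P5CS1 of proline synthesis (-0.90 ± 0.13, and -0.12 on its other probe) and the plastid beta-amylase gene BAM3 (-1.50 ± 0.19) were lower. PIF3 (-0.92 ± 0.09) and PIF1 (-0.75 ± 0.15), both phytochrome-interacting factors, were lower on their brightest probes, while their other probes gave -0.18 and -0.08 (PIF1 with the mean of a gene's probes -0.42, adjusted p = 0.0616). Lower too were 4CL1 (-0.75 ± 0.09) and MYB111 (-0.49 ± 0.10) of the phenylpropanoid list. PDC2, a pyruvate decarboxylase gene, was 4.72-fold higher (2.24 ± 0.16), and HRA1 of the low-oxygen list was higher too (0.71 ± 0.12). PR5 (1.41 ± 0.20) and VSP1 (1.99 ± 0.33) were higher among the 9 measured defence and jasmonate genes, whose median was -0.06 and whose mean was 0.34. Of 9 measured root markers, 3 were higher and 2 lower (6 and 2 adjusted over the list alone), with a median of 1.1 (adjusted p of the list = 0.104). COBL9, a root hair gene, was 4.22-fold higher (2.08 ± 0.28), and SHR, a regulator of root radial patterning, was lower (-0.83 ± 0.10). The remaining lists passed neither test at 2 h. Their medians were 0.07 for cold response, 0.12 for heat shock and -0.22 for photosynthesis, with no member called.

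In total 1365 genes were higher and 1678 lower in Alc::LHY at 2 h, and 3038 of these 3043 genes had the same sign on both arrays. Of those that differed by over 1 log2 unit 548 were higher and 333 lower. The count fell to 504 without the replicate S array of that time (306 higher and 198 lower) and to 603 without the replicate I array (430 and 173), which turned the balance. With median centring in place of loess it was 0 in limma, with 2980 genes at an unadjusted p under 0.05. That scaling moved the median ratio of all genes to between -0.12 and 0.11 depending on the time.

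**Figure D1:**
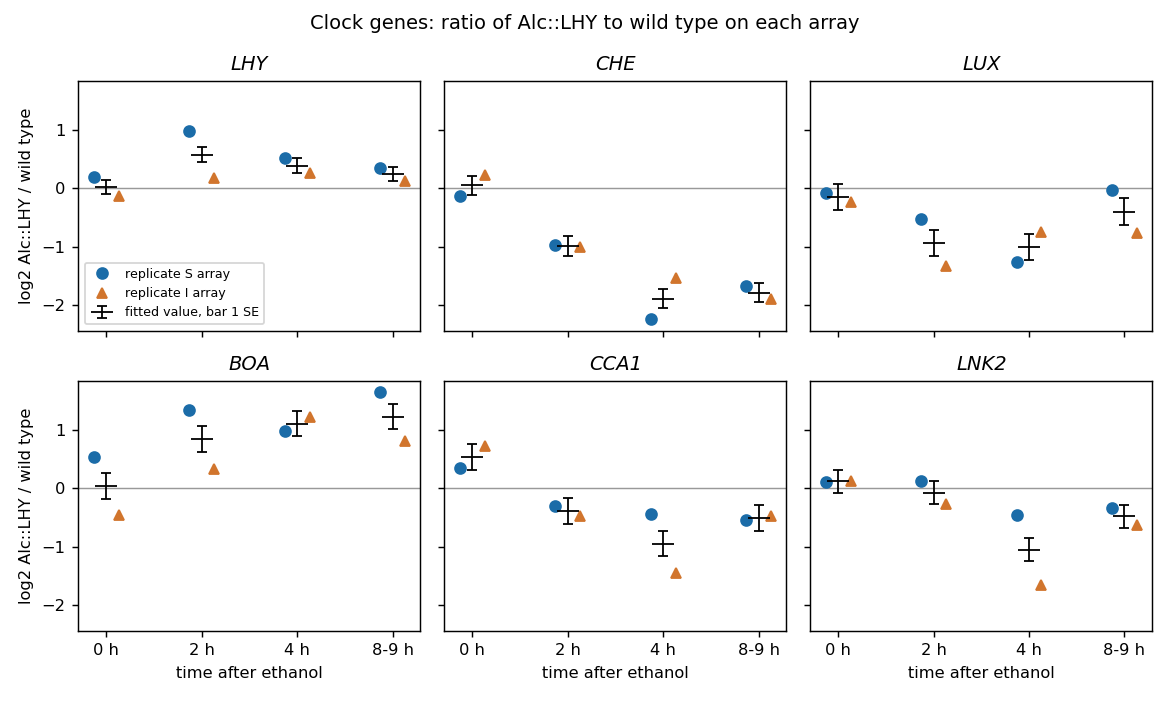
Ratio of Alc::LHY to wild type (log2, vertical axis) against time after ethanol (horizontal axis) for 6 clock genes. Circles and triangles are the arrays of replicates S and I, and the black marks give the fitted value with a bar of 1 SE. CHE lies at -0.98 at 2 h and -1.88 at 4 h, while BOA lies at 1.1 at 4 h and 1.22 at 8-9 h.

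At 4 h EXPA8, an expansin gene, was 7.87-fold lower (-2.98 ± 0.15, adjusted p = 0.000177), and the xyloglucan-modifying enzyme genes XTH6 (-2.71 ± 0.31) and XTH24 (-2.57 ± 0.24) were lower as well. LHCB2.2 (-2.78 ± 0.37), LHCB2.3 (-2.74 ± 0.34) and LHB1B1 (-2.72 ± 0.26), which encode chlorophyll-binding proteins of the photosystem II antenna, lay in the same range. RPT2, a phototropism gene, stood at -2.55 ± 0.25, and the transcript without a gene name that was lower at 2 h stood at -2.61 ± 0.15. After TA44692_3702, the highest ratios at 4 h were again those of SBTI1.1 (55.5-fold, 5.79 ± 0.15), AT4G29640 (at least 50.5-fold), AT5G62730 (5.15 ± 0.25), AT3G63360 (4.91 ± 0.15) and EXL4 (4.75 ± 0.23), with AT1G12630 (4.59 ± 0.28) and the unnamed TC402207 (4.39 ± 0.22).

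Of the 14 evening and daytime clock genes, 4 were lower and 1 was higher at 4 h (2 and 1 adjusted over the list alone). Over all genes tested 36.7% were called at 4 h, the share to set beside each list count. CHE was 3.69-fold lower (-1.88 ± 0.17, adjusted p = 0.000631), followed by LUX (-1.0 ± 0.22), PRR5 (-0.72 ± 0.22) and PRR7 (-0.49 ± 0.16). BOA, a homologue of LUX, was 2.15-fold higher (1.1 ± 0.22, adjusted p = 0.00974). Of the 13 morning genes, 5 were lower and 1 was higher (5 and 1 adjusted over the list alone). CCA1, the closest relative of LHY, was lower (-0.94 ± 0.22, adjusted p = 0.0168), with -0.44 on the replicate S array and -1.45 on that of replicate I. RVE1 (-1.04 ± 0.22), RVE7 (-0.57 ± 0.10), RVE8 (-0.76 ± 0.14) and the co-activator gene LNK2 (-1.05 ± 0.19) were lower, and RVE5 (AT4G01280) was higher (0.58 ± 0.10). The other probe of RVE7 gave 0.05 and that of PRR7 -0.14. With the mean of a gene's probes both lost the call (-0.26, adjusted p = 0.0631, and -0.32, adjusted p = 0.129). The probe nearest 0 gave -0.39 for LUX, -0.39 for RVE1 and -0.32 for LNK2, which kept their calls with the mean of a gene's probes. LNK3 had opposite signs on the arrays, 0.82 in replicate S and -1.87 in replicate I. Neither clock list passed as a whole (adjusted p = 0.164 and 0.103). With median centring CHE remained called among these genes (-2.15, adjusted p = 0.027). The other calls were lost with ratios of the same sign. They were -1.18 for LUX, -0.78 for PRR5, -0.74 for PRR7, 0.94 for BOA, -1.18 for CCA1, -1.23 for RVE1, -0.78 for RVE7, -0.97 for RVE8, -1.29 for LNK2 and 0.37 for RVE5 (adjusted p from 0.0734 for RVE1 to 0.487 for RVE5).

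Photosynthesis genes stood lower together at 4 h, with 15 of 21 lower and none higher (15 adjusted over the list alone), a median of -1.17 and an adjusted p of 2.38e-05 (adjusted p = 0.614 with an estimated correlation). LHCB2.1 (-1.65 ± 0.15), LHCB4.2 (-1.50 ± 0.15), LHCB1.3 (-1.79 ± 0.15) and LHCB1.1 (-1.80 ± 0.22) had the smallest p. In the phenylpropanoid and flavonoid pathway 12 of 16 genes were lower (13 adjusted over the list alone), with a median of -0.91 and an adjusted p of 1.34e-05 (adjusted p = 0.614 with an estimated correlation). These included PAL1 (-1.57 ± 0.17), which opens the pathway, 4CL1 (-1.32 ± 0.09), the flavonol synthase gene FLS1 (-1.18 ± 0.09) and the chalcone isomerase gene CHI (AT3G55120, -0.83 ± 0.10). Among PIF, shade and auxin growth genes 8 of 10 were lower (8 adjusted over the list alone, median -0.75, adjusted p = 0.00857, and adjusted p = 0.614 with an estimated correlation), with PIF4 at -1.97 ± 0.31, PIF1 at -1.43 ± 0.15, XTR7 at -1.05 ± 0.22 and PIF3 at -0.67 ± 0.09. Of 12 genes of ABA synthesis and breakdown 5 were lower (5 adjusted over the list alone, median -0.40, adjusted p = 0.037, and adjusted p = 0.614 with an estimated correlation). NCED4 stood at -2.26 ± 0.12, the glucosidase gene BG1 at -1.02 ± 0.26, the ABA-degrading CYP707A3 at -0.69 ± 0.17 and the aldehyde oxidase gene AAO3 at -0.46 ± 0.11. The cold response list stood higher, with 4 of 10 genes higher (6 adjusted over the list alone, median 0.82, adjusted p = 0.00986, and adjusted p = 0.614 with an estimated correlation). COR6.6 was 11.2-fold higher (3.48 ± 0.34), KIN1 10.9-fold (3.45 ± 0.47), and RD29A, which ABA and drought also induce, and COR413-PM1 were higher as well (1.96 ± 0.39 and 1.04 ± 0.25). All 5 list calls were thereby lost in the repeat with an estimated correlation, which also rests on 3 residual degrees of freedom.

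The other lists did not pass at 4 h, while single members did. COL2 (-2.21 ± 0.18) and CDF1 (AT5G62430, -1.32 ± 0.14) were among 6 of 16 clock outputs that were lower (6 adjusted over the list alone). In ABA signalling 6 genes were lower and 2 higher (6 and 2 adjusted over the list alone), with PYL4 at -1.53 ± 0.16 and HAI2 at 2.63 ± 0.28. Of the 11 ABA and drought response genes RD22 (-0.89 ± 0.12) and P5CS1 (-0.51 ± 0.13) were lower and 1 was higher (list median 0.10, mean 0.23). The other probe of P5CS1 gave 0.27, and the call was lost with the mean of a gene's probes (-0.12, adjusted p = 0.481). The other probe of RD22 gave -0.11. PDC2 (1.27 ± 0.16) and HRA1 (0.74 ± 0.12) were higher in the low-oxygen list, in which 4 of 15 genes were higher and 3 lower. The starch genes BAM3 (-1.34 ± 0.19) and GBSS1 (-2.03 ± 0.34) were lower, while 2 of the 12 were higher (list median -0.01). The small heat shock protein genes HSP17.4 (1.3 ± 0.33) and HSP17.6A (0.83 ± 0.26) were higher among 3 of 10 in their list, and 0 passed when adjusted over the list alone. PR5 was higher (0.65 ± 0.20). Of the root markers 4 were lower and 1 higher (median -0.81, adjusted p of the list = 0.0665), with SHR at -1.22 ± 0.10 and SCR, which acts with SHR, at -1.03 ± 0.13. The other probe of SCR gave 0.11.

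Across all genes 3719 were higher and 4168 lower at 4 h, of which 693 and 1139 differed by over 1 log2 unit. The count was 3277 without the replicate S array of that time and 3901 without the replicate I array. Median centring in place of loess left 1443 calls, of which 23.7% were higher, against 47.2% of the calls after loess.

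**Figure D2:**
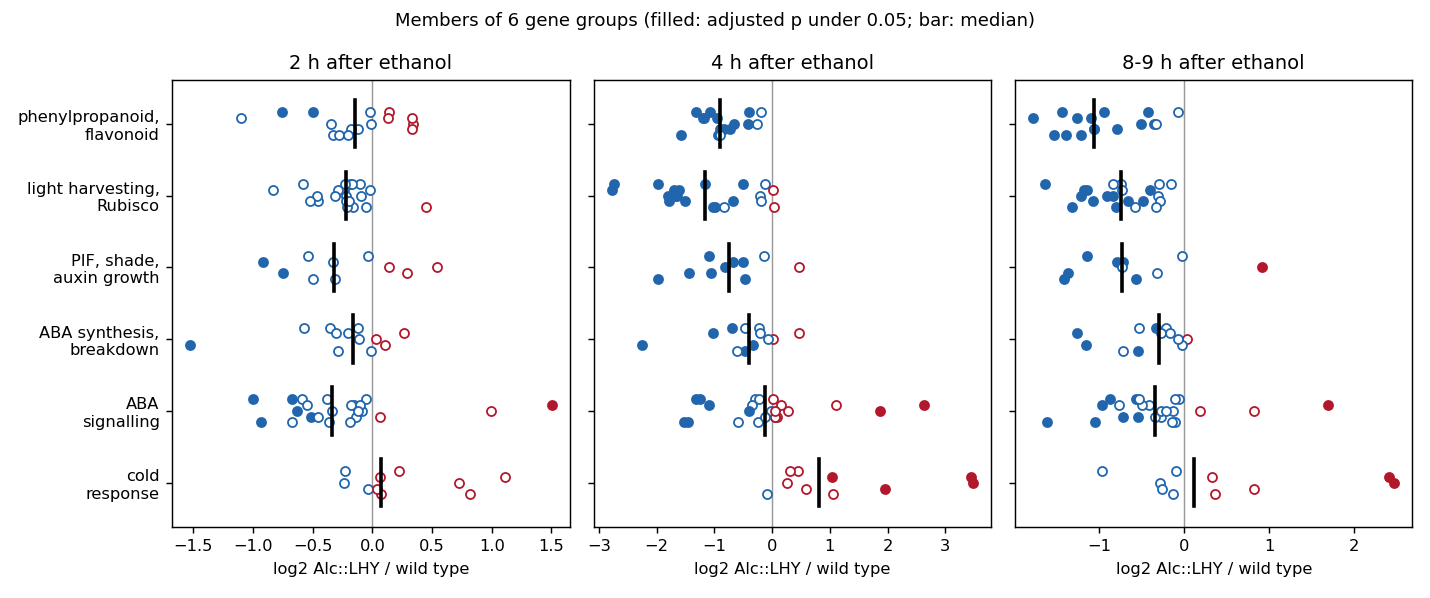
Log2 ratio of Alc::LHY to wild type (horizontal axis) for each measured member of 6 gene groups at 2, 4 and 8-9 h. Filled circles passed the threshold, open circles did not, red and blue mark higher and lower, and the black bar is the median. The median of the phenylpropanoid and flavonoid genes lay at -0.15 at 2 h, -0.91 at 4 h and -1.06 at 8-9 h.

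At 8-9 h MAM1, which acts in methionine chain elongation for aliphatic glucosinolates, was 5.70-fold lower (-2.51 ± 0.20, adjusted p = 0.000467), and CYP79F1, which acts on the elongated chains, was lower (-2.45 ± 0.29). AT3G28899, which was already lower at 0 h, was lower by at least 7.98-fold, followed by DCF, an acyltransferase gene of cutin synthesis (-2.65 ± 0.22), AT14A (-2.56 ± 0.27), LHB1B1 (-2.40 ± 0.26), AT2G05540 (-2.35 ± 0.61) and AT1G54010 (-2.35 ± 0.27). SBTI1.1 stood 51.4-fold higher (5.68 ± 0.15) and EXL4 36.2-fold higher (5.18 ± 0.23). High ratios were also measured for AT4G29640 (at least 45.4-fold), AT1G12630 (4.71 ± 0.28), EMB3120 (4.51 ± 0.25), the expansin gene EXPA20 (4.47 ± 0.14) and the MADS-box gene AGL86 (at least 22.1-fold).

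At 8-9 h BOA was higher (1.22 ± 0.22, adjusted p = 0.00639) and CHE lower (-1.78 ± 0.17, adjusted p = 0.000707) among the 14 evening and daytime genes (1 and 1 adjusted over the list alone). Over all genes tested 36.7% were called at that time. Of the 13 morning genes RVE5 (AT4G01280) was higher (0.49 ± 0.10) and none was lower (1 and 0 adjusted over the list alone). CCA1 had a ratio of -0.51 (adjusted p = 0.115) and LNK2 of -0.48 (adjusted p = 0.101). With median centring BOA (1.44, adjusted p = 0.0864), CHE (-1.51, adjusted p = 0.0718) and RVE5 (0.78, adjusted p = 0.182) kept their sign and lost the call.

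The phenylpropanoid and flavonoid genes had the lowest median of the 15 fixed lists at 8-9 h, with 14 of 16 lower (15 adjusted over the list alone, median -1.06, adjusted p = 8.29e-06, and adjusted p = 0.487 with an estimated correlation). 4CL1 (-1.43 ± 0.09), PAL1 (-1.38 ± 0.17), FLS1 (-1.09 ± 0.09) and CHI (-1.06 ± 0.10) had the smallest p. Of 21 photosynthesis genes 12 were lower (14 adjusted over the list alone, median -0.74, adjusted p = 0.00034, and adjusted p = 0.613 with an estimated correlation), with LHCB2.3 at -1.63 ± 0.34 and LHCB1.1 at -1.21 ± 0.22, LHCB1.3 at -1.07 ± 0.15 and LHCB2.1 at -0.83 ± 0.15. Among PIF, shade and auxin growth genes 6 were lower and 1 higher (7 and 1 adjusted over the list alone, median -0.72, adjusted p = 0.0304, and adjusted p = 0.487 with an estimated correlation), with PIF1 at -1.36 ± 0.15, PIF3 at -0.79 ± 0.09, HFR1 at -1.14 ± 0.23 and the auxin-response gene IAA19 at -0.72 ± 0.12. ABA signalling was lower (7 of 23 lower and 1 higher, 7 and 1 adjusted over the list alone, median -0.34, adjusted p = 0.0304, and adjusted p = 0.487 with an estimated correlation), with the receptor genes PYL4 (-1.61 ± 0.16), PYR1 (-0.96 ± 0.15) and PYL6 (-0.87 ± 0.14) lower and HAI2 (1.69 ± 0.28) higher. ABA synthesis and breakdown was lower (4 of 12, 5 adjusted over the list alone, median -0.30, adjusted p = 0.0459, and adjusted p = 0.487 with an estimated correlation), with BG1 at -1.26 ± 0.26, NCED4 at -1.15 ± 0.12, AAO3 at -0.54 ± 0.11 and ABA2 at -0.33 ± 0.09. No list call of the genotype comparisons held with an estimated correlation. That repeat also rests on 3 residual degrees of freedom, so it does not show the correlation as the reason.

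Among the lists that did not pass at 8-9 h, COL2 (-1.84 ± 0.18) and CDF1 (-1.15 ± 0.14) were lower in the clock outputs, of which 6 of 16 were lower (6 adjusted over the list alone). COR6.6 (2.47 ± 0.34) and KIN1 (2.41 ± 0.47) were the 2 cold response genes that were higher. RD22 (-1.15 ± 0.12) and P5CS1 (-0.88 ± 0.13) were lower, as were the starch genes BAM3 (-1.22 ± 0.19) and PHS1 (-0.68 ± 0.12) among 5 of 12. PDC2 was 3.16-fold higher (1.66 ± 0.16) and ALDH2B4, an aldehyde dehydrogenase gene, lower (-0.44 ± 0.10, and -0.31 with adjusted p = 0.0724 for the mean of its probes), in a list with 3 genes higher and 4 lower. HSP17.4 (1.31 ± 0.33) and PR5 (1.33 ± 0.20) were higher, and LOX2, a lipoxygenase gene of jasmonate synthesis, was lower (-1.57 ± 0.33). Of the root markers COBL9 was 6.54-fold higher (2.71 ± 0.28) and SHR lower (-1.17 ± 0.10), with a list median of -0.29. The median, mean and test of a list differed in sign for evening and daytime clock genes (median 0.04, mean -0.07) and for defence genes (median -0.06, mean 0.02).

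In all, 3600 genes were higher and 4285 lower at 8-9 h. Without the 9 h array of replicate S the count was 3548, and without the 8 h array of replicate I it was 1936. Taking each as its own time is the same fit as leaving out the other, so it is no separate check. Median centring left 285 calls, of which 76.1% were higher, against 45.7% of the calls after loess.

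**Figure D3:**
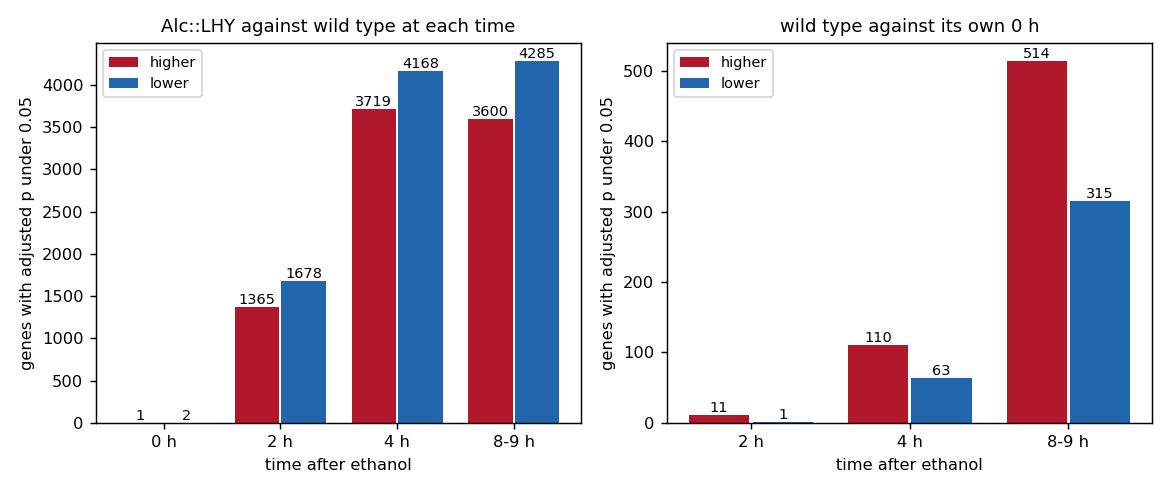
Number of genes with an adjusted p under 0.05 (vertical axis, from 0) for Alc::LHY against wild type at each time, on the left, and for wild type against its own 0 h, on the right. Red bars are genes that were higher and blue bars genes that were lower, from 1 and 2 genes at 0 h to 3600 and 4285 genes at 8-9 h in the comparison of the lines.

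Relative to the lines' difference at 0 h, SBTI1.1 rose most among the called genes at 2 h (5.22 ± 0.21, adjusted p = 0.000462), followed by AT5G62730, EXL4, AT4G29640 and AT3G63360. MYB47 (-2.15 ± 0.28), AT1G52000 (-2.04 ± 0.26, and -1.75 with adjusted p = 0.0513 for the mean of its probes), the ferric reductase-like gene FRO8 (-1.99 ± 0.19), AT1G68570 (-1.95 ± 0.23) and AT1G60590 (-1.91 ± 0.19) fell most. By 4 h the ratio of LHCB2.3 had fallen by 12.7-fold (-3.67 ± 0.48), with those of LHCB2.2 (-3.27 ± 0.52), EXPA8 (-2.97 ± 0.21), LHB1B1 (-2.78 ± 0.37) and the unnamed TA26725_3702 (-2.75) next. A falling ratio need not be a falling level in Alc::LHY. From 0 h to 4 h the mean log2 level of LHCB2.3 went from 11.69 to 11.45 in Alc::LHY and from 10.76 to 14.18 in wild type. That of EXPA8 went from 11.47 to 8.7 in Alc::LHY and from 11.48 to 11.68 in wild type. Of the clock genes CHE (-1.93 ± 0.23), CCA1 (-1.48 ± 0.31), LNK2 (-1.17 ± 0.28), RVE8 (-0.88 ± 0.19) and RVE5 (0.53 ± 0.14) passed at 4 h, and CHE (-1.83 ± 0.23) and BOA (1.19 ± 0.31) at 8-9 h. By 8-9 h the ratios of MAM1 (-2.83 ± 0.28), CYP79F1 (-2.76 ± 0.41), CYP83A1 (-2.60 ± 0.38), AT14A (-2.69 ± 0.38) and GSTF12, a glutathione transferase gene of anthocyanin transport (-2.68 ± 0.62), had fallen most. From 0 h to 8-9 h the level of GSTF12 went from 10.74 to 10.44 in Alc::LHY and from 10.02 to 12.4 in wild type. That of MAM1 went from 12.2 to 10.4 in Alc::LHY and from 11.87 to 12.91 in wild type. The largest rises to 4 h and to 8-9 h are not listed here. Among called changes over 1 log2 unit, 546 were rises and 1090 falls to 4 h, and 533 and 1193 to 8-9 h.

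In this comparison the ratios of 439 genes rose and of 447 fell from 0 h to 2 h, 1460 and 2256 to 4 h, and 1561 and 2545 to 8-9 h. The balance at 2 h depended on the processing. Of the changes over 1 log2 unit at 2 h, 361 were rises and 236 falls. For all calls it was 316 and 57 with an intensity trend, 432 and 203 with the scanner software's ratio, 125 and 45 or 213 and 27 without the replicate S or I array of 0 h, and 108 and 9 or 187 and 12 without that of 2 h. The photosynthesis list passed at 2, 4 and 8-9 h (adjusted p = 0.0211, 3.87e-06 and 7.92e-05, and adjusted p = 0.723, 0.612 and 0.549 with an estimated correlation). The phenylpropanoid list passed at 4 and 8-9 h (adjusted p = 3.87e-06 and 7.04e-06, and adjusted p = 0.612 and 0.454 with an estimated correlation). ABA signalling and starch genes passed at 2 h (adjusted p = 0.0434 for each, and adjusted p = 0.723 with an estimated correlation). PIF and shade genes passed at 4 and 8-9 h (adjusted p = 0.00732 and 0.0387, and adjusted p = 0.612 and 0.454 with an estimated correlation). Clock outputs, cold response and ABA synthesis genes passed at 4 h (adjusted p = 0.044, 0.0313 and 0.0393, and adjusted p = 0.612, 0.681 and 0.612 with an estimated correlation). Root markers passed at 2 h (median 1.23, adjusted p = 0.0437, and adjusted p = 0.723 with an estimated correlation), with 1 gene higher and 1 lower over all genes, and 6 and 2 adjusted over the list alone. With median centring all 3 counts were 0 in limma, with 1453, 2889 and 2126 genes at an unadjusted p under 0.05. Leaving out single arrays of the times compared gave 117 to 240 calls at 2 h, 1114 to 2295 at 4 h and 509 to 2049 at 8-9 h.

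Between times after ethanol, few genes passed. FLS1 was lower at 4 h than at 2 h relative to wild type (-1.52 ± 0.13, adjusted p = 0.0439), and also at 8-9 h (-1.43 ± 0.13, adjusted p = 0.0413). The ratio rose in 2 genes and fell in 20 from 2 h to 4 h, and rose in 7 and fell in 29 from 2 h to 8-9 h. In these contrasts 3642 and 3778 genes had an unadjusted p under 0.05. The median of the root markers fell as well, from 1.1 at 2 h to -0.81 at 4 h and -0.29 at 8-9 h, without their list passing at any of these times. Whether the falling genes follow a share of root RNA was not tested. From 4 h to 8-9 h 0 genes passed in limma, with 1745 at an unadjusted p under 0.05. The ratios at different times come from different arrays, but the fit gives a gene the same estimate of spread at every time. A gene with a small spread is thus favoured for a call at each time. Sharing above that of independent lists is therefore partly built in. Of the genes that were lower at 4 h and at 8-9 h, 3190 were shared, where independent lists of these lengths would share 831.8, and 2608 higher genes were shared against 623.6. Between 2 h and 4 h 1533 lower genes and 1035 higher genes were shared, against 325.7 and 236.4, and 60 genes that were higher at 2 h were lower at 4 h. Across all genes the ratios correlated at 0.89 between 4 h and 8-9 h and at 0.76 between 2 h and 4 h.

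The wild-type plants give the course of expression over the same hours in continuous light after ethanol. Effects of time and of the ethanol treatment cannot be told apart in it. By 8-9 h the morning genes had risen, with LNK3 (5.13 ± 0.53), LNK4 (5.11 ± 0.56), CCA1 (20.7-fold, 4.37 ± 0.26) and LNK2 (4.26 ± 0.28) ahead of RVE3 (AT1G01520, 1.63 ± 0.23), RVE8 (1.57 ± 0.20), RVE1 (1.45 ± 0.30) and RVE7 (1.2 ± 0.18). RVE2 fell (-2.13 ± 0.44). LHY rose by at least 1.63-fold (adjusted p = 0.0199) on its dim probe. The evening genes BOA (-2.32 ± 0.38), ELF4 (-2.31 ± 0.45), PRR3 (-2.29 ± 0.28), TOC1 (-1.82 ± 0.23), LUX (-1.68 ± 0.28), PRR5 (-1.58 ± 0.24) and FKF1 (-1.03 ± 0.14) fell, while the daytime genes PRR7 (2.24 ± 0.25) and PRR9 (at least 2.15-fold) rose. Outside the clock LHCB2.3 (26.7-fold, 4.74 ± 0.40), COL2 (4.50 ± 0.27) and the unnamed TA26506_3702 (4.48 ± 0.33) rose most. AT5G23240 (-4.30 ± 0.32), the Rubisco assembly gene RbcX1 (-3.82 ± 0.43), CCL (-3.56 ± 0.54), the jumonji-domain gene JMJD5 (-3.32 ± 0.29) and AT2G33830 (-3.32 ± 0.66) fell most.

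Part of this course was present earlier. At 4 h CCA1 (3.53 ± 0.26), COL2 (3.51 ± 0.27), AT1G66100 (3.49 ± 0.43), LHCB2.3 (3.43 ± 0.40), the unnamed TA26506_3702 (3.25 ± 0.33), LNK2 (2.49 ± 0.28), RVE8 (1.69 ± 0.20) and RVE3 (1.61 ± 0.23) had risen, and FKF1 (-0.89 ± 0.14), AT5G23240 (-2.92 ± 0.32), CCL (-2.90 ± 0.54), JMJD5 (-2.68 ± 0.29), RbcX1 (-2.49 ± 0.43) and AT1G07050 (-2.19 ± 0.39) had fallen. At 2 h AT1G19380 (3.58 ± 0.44), AT4G21870 (3.21 ± 0.34), the transcription factor gene WRKY22 (1.77 ± 0.22), the ABA receptor gene PYL6 (1.56 ± 0.15) and the auxin transporter gene ABCB21 (1.46 ± 0.16) were higher than at 0 h, and AT1G19660 was lower (-0.86 ± 0.11, and -0.56 with adjusted p = 0.134 for the mean of its probes). In Alc::LHY the rise of CCA1 to 8-9 h was 3.33 ± 0.26, that of LHCB2.3 2.17 ± 0.40 and that of COL2 2.49 ± 0.27.

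In wild type the estimated correlation entered the list test as a fixed value, so lists that held here cannot be set against those lost in the genotype comparisons. Of the 13 morning genes measured in wild type, 8 rose and 1 fell by 8-9 h (9 and 1 adjusted over the list alone, adjusted p = 2.37e-24, and adjusted p = 1.01e-06 with an estimated correlation). Of the 13 evening and daytime genes 7 fell and 2 rose (7 and 3 adjusted over the list alone, adjusted p = 1.01e-05, and adjusted p = 0.0414 with an estimated correlation). The clock outputs (9 of 16 rose and 2 fell, 10 and 4 adjusted over the list alone) and the photosynthesis genes (9 of 20 rose, 13 and 1 lower adjusted over the list alone) stood higher, with adjusted p = 5.47e-10 and 0.00651 with an estimated correlation. Starch genes stood lower, with 7 of 12 lower and 1 higher (9 and 1 adjusted over the list alone, adjusted p = 6.82e-05 with an estimated correlation), and 3 of 10 PIF and shade genes rose (4 adjusted over the list alone, adjusted p = 0.00147 with an estimated correlation). The phenylpropanoid genes passed at 8-9 h (2 of 16 rose, 6 and 1 adjusted over the list alone, adjusted p = 0.0237) and lost the call (adjusted p = 0.612 with an estimated correlation). At 4 h the morning, output, photosynthesis and starch lists held with an estimated correlation (adjusted p = 5.24e-06, 1.11e-07, 0.0148 and 6.7e-07 with an estimated correlation). The evening list (adjusted p = 0.0503 with an estimated correlation), the phenylpropanoid list (adjusted p = 0.0503 with an estimated correlation) and the defence list (adjusted p = 0.447 with an estimated correlation) passed only at the preset correlation. At 2 h the morning, output and heat shock lists stood higher and the starch list lower (adjusted p = 0.01, 0.00689, 0.00689 and 0.00078). None of them held (adjusted p = 0.489, 0.145, 0.489 and 0.145 with an estimated correlation). Root markers then stood lower in wild type than at 0 h (median -1.22, adjusted p = 0.00133, and adjusted p = 0.366 with an estimated correlation), with no member past the threshold over all genes and 4 lower when adjusted over the list alone.

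The threshold was passed in wild type by 12 genes at 2 h (11 higher and 1 lower), 173 at 4 h (110 and 63) and 829 at 8-9 h (514 and 315). In Alc::LHY 3207, 6017 and 7369 genes differed from 0 h. The wild-type counts depended on single arrays, with 0 to 245 calls at 2 h, 1 to 325 at 4 h and 65 to 800 at 8-9 h when each array was left out. At 2 h the count was 0 in limma without the replicate S array of 0 h, with 1465 genes at an unadjusted p under 0.05, and 245 without the replicate I array of 2 h. At 4 h it was 1 without the replicate S array of 0 h and 325 without the replicate S array of 4 h. At 8-9 h it was 65 without the 9 h array, 187 without the 8 h array, and 93 and 172 without the replicate I and S arrays of 0 h. Without the replicate term the counts were 5, 22 and 352. The balance of higher and lower genes turned as well. At 2 h it was 22 and 68 without the replicate S array of 2 h and 5 and 10 without the replicate I array of 0 h. At 4 h it was 150 and 175 without the replicate S array of 4 h and 9 and 15 without the replicate I array of 0 h. At 8-9 h quantile normalization gave 356 and 358.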

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

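Of the tests below, the 4 on LHY and TA44692_3702 and the correlation of the 4 h ratios with the wild-type course were chosen after the result was seen. The difference between the lines changed from 0 h in 886 genes at 2 h, 3716 at 4 h and 4106 at 8-9 h, by a test of the change itself. It also differed between 2 h and 4 h in 22 genes and between 2 h and 8-9 h in 36 genes. FLS1, the flavonol synthase gene, is the only member of the fixed gene lists that changed in both, by -1.52 ± 0.13 to 4 h (adjusted p = 0.0439) and -1.43 ± 0.13 to 8-9 h (adjusted p = 0.0413).

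At 2 h the ratio of TA44692_3702 was 6.33 and that of the LHY probe 0.57, or 0.81 without background subtraction and 2.51 with the scanner software's ratio, which also differs in the dye correction. A swap of lines or dyes on single arrays is argued against, as the lowest correlation across genes between replicates after ethanol was 0.65. A probe that reports little of the LHY transcript stays open, as CCA1 rose by 3.58 log2 units more in wild type by 8-9 h while the LHY probe stood at background at 0 h, which makes this gap an upper bound. LHY had 1 probe on the array, so a small rise of LHY itself cannot be told apart from a poor probe. The rise is not shown to be small either, as its size depended on the processing (0.57 against 2.51). At 2 h the Alc::LHY signal in replicate S was 191 with a background of 65, and the wild-type signal 43 with 36. In replicate I, with swapped dyes, they were 56 with 32 and 82 with 63. The background correction added an offset of 50 to both dyes, and a constant added to both shrinks the ratio of such dim signals before loess. In replicate S the wild-type signal of 43 stood above its background of 36 by less than this offset. The value of 0.57 is therefore no measure of how small the rise was. How much of the gap between 0.57 and 2.51 the offset accounts for was not tested. TA44692_3702 could be carried by the transgene, with a lowest log2 ratio of 5.39 on the 6 arrays after ethanol, but this stays open, as its sequence is not in the files and its wild-type values varied (2.36 from 0 h to 2 h, adjusted p = 0.287, with a level of 10.65 on the replicate I array at 2 h).

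At 2 h 3 of 9 root markers were higher in Alc::LHY and 2 lower, with a median of 1.1, and the list did not pass (adjusted p = 0.104). A larger share of root RNA may raise such genes, and a second list was tested for it. Its 18 inner-tissue and uptake genes had a median of 0.34 (14 above 0, 5 called) and its 6 root hair genes 0.214 (0 called), short of the 0.5 set for both parts, and the first is above the 0.25 set against. The inner-tissue genes went the other way at 4 h (median -0.493, 3 of 18 above 0, 1 called higher and 9 lower), and in wild type they stood at -0.748 from 0 h to 2 h (0 of 18 above 0, none called), so this stays open. On the 2 arrays the root marker median was 0.33 and 1.84, so the lower value of 0.33 neither excludes nor shows the effect of a single array, and no biological explanation was tested.

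Genes that rose in wild type by 8-9 h stood lower in Alc::LHY at 4 h, with 290 of 514 called lower, 40 called higher and a median of -0.52. Noise shared through the wild-type channel is argued against by the design, as the 4 h difference and the wild-type change have no array in common. Across all genes they correlated at -0.17, which restates the pattern and is no separate test. With mean intensity taken out of both, the correlation was -0.165, which argues against probe brightness. A line at another clock phase stays open. The 315 genes that fell in wild type had a median of -0.12 at 4 h, below the bound of 0 set against it beforehand, so its prediction was not met. With an SD of 0.67 and 62 called higher and 71 lower these genes went both ways. For that reason, and by a looser rule than the one set beforehand, another phase was not taken as excluded.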

How the results depend on the processing

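All alternatives were planned, and none was chosen after the values were seen. Direction was compared only for values called in either fit, so uncalled values may have changed sign. The values kept include 367 with Aquantile after loess, which leaves the ratios as they are. Of the named-gene values, 7870 kept their side of the threshold, 664 lost the call, 69 gained it and 1 reversed. That was LNK3 (AT3G12320), genotype difference at 4 h, without the replicate I array of 4 h (0.75, adjusted p = 0.0383), against -1.805 without the replicate S array. Of the gene list values 164 kept their side, 15 lost it and 1 gained it. The cause of these moves was not tested, except where fewer arrays or genes explain them. Dim signals limit LHY and other probes near background.

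Replicates share only a label, a dye and a slide. Deviations from the time means correlated between times at -0.016 to 0.602, so a pairing is not shown. With no replicate block LHY at 2 h was 0.57 (adjusted p = 0.113), and the wild-type counts were 5, 22 and 352. The block moved no count of the genotype comparisons by over 1.5 times.

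Without background subtraction the counts were 11 at 0 h, 1385 for the change to 2 h and 20 for wild type at 2 h, and LHY was 0.81 at 2 h and 0.50 at 4 h (adjusted p = 0.00411 and 0.013). The scanner software's ratio gave 20 genes at 0 h, 2291 for the change to 8-9 h, and LHY at 2.51 at 2 h (adjusted p = 0.00169), 1.18 at 4 h and 0.58 at 8-9 h, and the authors' matrix gave 20, 2293, 2.51, 1.18 and 0.58. Median centring gave 0, 0, 1443 and 285 genes at 0, 2, 4 and 8-9 h and 0, 0 and 0 for the changes (limma, unadjusted p under 0.05 in 86 and 2980 genes at 0 and 2 h and in 1453, 2889 and 2126 for the changes). It put LHY at 2 h at 0.67 (adjusted p = 0.243) and 51 named genes were called, against 157. An intensity trend gave 0 genes at 0 h (limma, 514 at an unadjusted p under 0.05), 373 for the change to 2 h and LHY at 4 h at 0.38 (adjusted p = 0.0473). Wild type at 2 h had 21 genes with quantile normalization and 7 with the strict filter. The 8 h array alone gave 3548 genes, 1798 for the change and 65 in wild type, and the 9 h array alone gave 1936, 509 and 187. With an estimated correlation, and a test resting on 3 residual degrees of freedom, 0 of 13 gene list calls of the genotype comparisons held.

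Leaving out each array gave 0 to 3 genes at 0 h, 504 to 3083 at 2 h, 3277 to 7740 at 4 h and 1936 to 7842 at 8-9 h. The changes from 0 h ranged over 117 to 895, 1114 to 2929 and 509 to 4014, and wild type over 0 to 245, 1 to 325 and 65 to 800. LHY ranged over -0.03 to 0.07, 0.30 to 0.84, 0.29 to 0.48 and 0.12 to 0.36 at the 4 times, and 127 to 153 named genes were called. The LHY call at 2 h was lost without either array of 2 h or of 8-9 h. A lone array is assumed to vary like the others, and channel fits without an array use the intraspot correlation of all arrays (0.333).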

Other observations

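The 3 gene groups here were chosen after their values were seen. They had no set test. Of all genes tested 14.2% were called at 2 h and 36.7% at 4 h and at 8-9 h. Of 17 glucosinolate synthesis genes 7 were called lower in Alc::LHY at 2 h, 14 at 4 h and 14 at 8-9 h, and none higher. Their medians were -0.67, -1.59 and -1.64. MYB29, a regulator of aliphatic glucosinolate genes, stood at -1.59 at 4 h and -1.98 at 8-9 h, and CYP79B3 of the indole branch at -2.35 and -2.07. MYB51, MAM3 and SOT16 were not called at any time. MAM3 stood above 0 at 2 h (0.64) and at 8-9 h (0.34), and SOT16 at 2 h (0.10). At 0 h no gene of the 3 groups was called.

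In sulfate assimilation 7 of 12 genes were lower and 2 higher at 4 h. APS4 stood at 4.04 and SERAT1;1 at 3.26, while APS3 stood at -1.64 and SERAT2;1 at -1.54. Among 13 expansin and xyloglucan-modifying enzyme genes 11 were lower at 4 h, with EXPA1 at -2.26, and only EXPA20 was higher (4.17).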
